A study of Mus musculus with 22 samples.

How the data were processed

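Bulk RNA sequencing libraries of 22 mice were compared, 11 from males and 11 from females. Per the labels' protocols, the animals were 8 weeks old and were taken 6 weeks after tamoxifen by oral gavage, total RNA was prepared with a Qiagen kit, messenger RNA was isolated and libraries were built with a NEBNext Ultra II kit. All animals carried a floxed Smc3 gene. Animals with a tamoxifen-dependent Cre driven by the Camk2a promoter, which is active in forebrain excitatory neurons, are called cKO in the labels, and animals without it WT. Each animal has its own number, no number occurs in more than one group, and no sequencing batch is given, so no pairing or batch term was available. One count column carries the number 20 while one title reads as cKO2 with a hyphen. That column was used as a replicate of female cKO, the group its name shows, without tying it to a title.

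The values are whole-number counts of reads per gene, as deposited by the authors in one table per sex with the same 20565 genes in both. Per the submitters' processing notes, the tools named are cutadapt, STAR, HTSeq and DESeq2 and the genome build is GRCm39. Their order, their versions, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes, and of family members with shared exons, may therefore have been assigned to either gene or left out. No position is printed, because the reference annotation at hand is of build GRCm38. The 22 columns of counts normalized by the authors were not used. Each table also holds the authors' deposited log2 fold change, p-value and adjusted p-value per gene, which are quoted where they are named as such. Gene names are those of the files, and 22 genes without a name kept their identifier.

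Totals were 12771354 to 16896239 counts per library. They limit the precision for genes of low abundance, and counting intervals would cover counting error only. Of 50 pairs of replicates, the lowest chi-square per degree of freedom over genes was 6.28, so no pair of libraries agreed within sampling noise.

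Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), scaled by TMM factors and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Each sex was fitted alone. The difference between sexes was the genotype by sex term of one fit of all 22 libraries. Fold changes are given as cKO minus WT on the log2 scale, as labelled, with a standard error taken as the fold change over the square root of F. Levels are CPM, the counts relative to the TMM-scaled library total, given as mean ± SD.

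A set of 51 gene lists was written before the data were examined, with 1204 of 1288 entries found in the tables. They cover receptors, channels, synaptic and adhesion genes, stress and activity genes, regions and the cell types that cortical tissue holds. Lists were tested with camera over genes with a mean normalized count of at least 10. The preset correlation between genes of 0.01 was the main setting, and the test was repeated with the correlation estimated from the libraries, with adjustment over all lists of a comparison. Lists with too few measured members were left out, so 50 were tested. Member counts are given over all genes tested and adjusted over the list alone. Overlap between sexes was tested with a 2-sided Fisher's exact test per direction. The correlation of fold changes is across genes, which are not independent replicates, and has no p-value.

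Genes named in the text follow a rule fixed before the data were examined. In each sex it takes Smc3, then the 8 largest rises and the 8 largest falls among genes past the threshold with a mean normalized count of at least 50 and a symbol that is no predicted model. It then takes the 3 members with the smallest p from each of up to 10 called lists, the 10 genes with the smallest p of the difference between sexes, and up to 10 genes changed in both sexes. Any other gene is said to have been chosen after its values were seen.

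The pipeline was tested on counts simulated from the real means, library sizes and dispersions with added changes. In the male design (15904 genes) it recovered 33.3% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 78.1% of those changed 3-fold. In the female design (15961 genes) the shares were 48.5%, 83.9% and 97.1%. For a change present in females alone, the test of the difference (16694 genes) recovered 23.1%, 56.9% and 88.6%. Of the calls, 2.42% in the male design, 3.77% in the female design and 8.06% for the difference were false. A list raised 1.5-fold was called in each design, and no other list was. Each gene was simulated on its own, so this does not show how often lists are called falsely when genes vary together. Nor does it show what share of changed genes is recovered then. Other groupings of the real libraries gave a median of 17 called lists in males and 19 in females with the preset correlation described above.

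Alternatives fixed beforehand were other thresholds, a minimum fold, other filters, DESeq2 1.42.0, RLE factors, one fit of all groups, Bonferroni adjustment, other settings of the list test and the correlation, and leaving out each library in turn. Other alternatives, among them a covariate holding each library's mean log2 CPM of oligodendrocyte markers, were chosen after seeing the data. In each comparison 99 other groupings of the same libraries, drawn with a fixed seed, were fitted to see how often they gave counts as large. Shares of 100 splits include the real grouping. GC content and length came from GENCODE vM21 transcripts, and the order of neighbouring genes from RefSeq on GRCm38.p6.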

Results

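The labels set out 4 groups of mice: 5 male WT, 6 male cKO, 5 female WT and 6 female cKO. The series title asks about a sex-specific role of SMC3, a core subunit of the cohesin ring that holds and folds chromatin, in forebrain neurons and anxiety-like behaviour. Total counts were 12771354 to 15028342 in the 11 male libraries and 13832715 to 16896239 in the 11 female libraries. Xist, the RNA of the inactive X chromosome, stayed at or below 0.938 CPM (counts relative to the library total) in male cKO and reached at least 586 CPM in female WT, and the Y-linked gene Ddx3y was at least 64.2 CPM in male WT and at most 0.320 CPM in female cKO.

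Sample titles name the hypothalamus while the tissue field names the prefrontal cortex. Genes that mark cortex over hypothalamus were abundant in these libraries. All 20 such genes reached a mean of at least 10 CPM in both sexes, with a median of 101 CPM in males and 99.1 CPM in females. Of 22 hypothalamus markers, 4 reached 10 CPM in each sex, 9 in males and 8 in females stayed under 1 CPM, and the median was 1.82 CPM in males and 1.88 CPM in females. Avp, the vasopressin gene of hypothalamic neurons, averaged 0.125 ± 0.147 CPM in male WT (SD, n = 5) and 0.235 ± 0.123 CPM in female WT (SD, n = 5). Of 20 striatum markers, 15 in males and 16 in females reached 10 CPM, and none stayed under 1 CPM. Their median was 18.2 CPM in males and 25.8 CPM in females. All of these are levels without a test.

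The total count of the targeted gene did not fall. Smc3 (ENSMUSG00000024974) was higher, not lower, in the libraries labelled cKO. In males it stood at 143 ± 15.4 CPM in cKO (SD, n = 6) and 83.2 ± 10.2 CPM in WT (SD, n = 5), a log2 fold change of 0.79 (SE 0.10, edgeR adjusted p = 0.00541). In females the values were 129 ± 10.2 CPM (SD, n = 6) and 73.7 ± 6.49 CPM (SD, n = 5), a log2 fold change of 0.81 (SE 0.07, edgeR adjusted p = 9.17e-05). The lowest library labelled cKO lay above the highest library labelled WT in each sex. In the authors' deposited table the log2 fold change of Smc3 was 0.79 in males and 0.81 in females. A gene total counts reads from any exon, so it does not show whether the floxed part was deleted, and all directions below are those of the labels. Arsi, the gene next to Camk2a and chosen after its values were seen, was also higher in every library labelled cKO, at 4.26 ± 1.02 against 0.731 ± 0.333 CPM in males and 3.63 ± 1.38 against 0.482 ± 0.176 CPM in females.

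**Figure D1:**
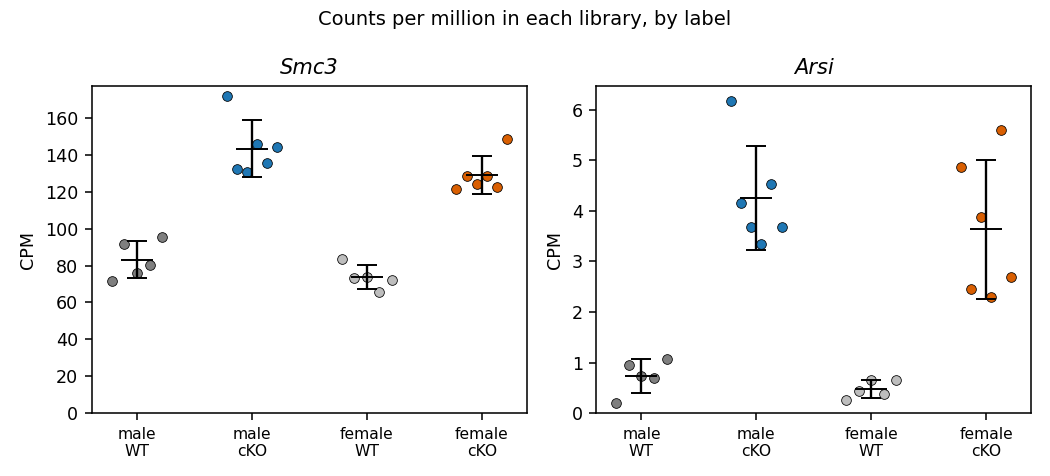
CPM (vertical axes) of Smc3 and of Arsi in each of the 22 libraries, by label. Points are libraries and bars are the mean and SD. The libraries labelled cKO average 143 CPM of Smc3 in males and 129 CPM in females, above every library labelled WT of the same sex.

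The male comparison asked which genes differ between the libraries labelled cKO and WT in males. Falls outnumbered rises among the called genes. Ier5l, an immediate early response family member, fell 5.64-fold, from 34.8 ± 9.13 CPM in WT (SD, n = 5) to 6.18 ± 1.92 CPM in cKO (SD, n = 6), a log2 fold change of -2.50 (SE 0.23, adjusted p = 0.00113). Htr1a, a serotonin receptor, fell 4.84-fold (log2 -2.28, SE 0.25, adjusted p = 0.00287), and Col6a2, a chain of collagen VI, fell 4.23-fold (log2 -2.08, SE 0.14, adjusted p = 4.23e-05). The somatostatin receptors Sstr1 and Sstr2 fell (log2 -2.04 and -1.89), as did the semaphorin receptor Plxnd1 (log2 -1.74), the inducible prostaglandin synthase Ptgs2 (log2 -1.69) and the cyclin-dependent kinase inhibitor Cdkn1c (log2 -1.68). Fewer genes rose. Rgs13, a regulator of G protein signalling, rose 4.02-fold from 1.37 ± 0.555 to 5.52 ± 1.70 CPM. The transcriptional corepressor Rcor2 rose by 0.79 on the log2 scale, the serine protease Masp1 by 0.78, the lipid transporter Abca7 by 0.59, the adaptor Bcar3 by 0.58, the gluconokinase Idnk by 0.55 and the glycolytic regulator Pfkfb3 by 0.55. Of 16098 genes tested, 13 rose and 81 fell, 94 in all, and 1528 had an unadjusted p under 0.05. The authors' deposited table holds 309 genes under an adjusted p of 0.05 in males.

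The male count depends on single libraries, and all but WT replicate 1 moved it by over 1.5 times. Without cKO replicate 8 it was 201, without cKO replicates 9, 10, 12, 13 and 14 it was 23, 25, 18, 60 and 27, and without WT replicates 3, 4, 5 and 6 it was 19, 18, 35 and 27. Of the 26 calls among named genes other than Smc3, 11 held with every library left out, namely Ier5l, Htr1a, Col6a2, Plxnd1, Cdkn1c, Rcor2, Wnt7b, Dpy19l1, Clcn2, St3gal1 and Ptpru. The other 15, which were Ptgs2, Sstr1, Sstr2, Rgs13, Masp1, Abca7, Bcar3, Idnk, Pfkfb3, Pyurf, Pcdha12, Adra2a, Adra2c, Efna5 and Robo3, each lost the call without at least 1 library. DESeq2 called 327 genes, 96 rising and 231 falling. One fit of all 4 groups called 276.

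Among the fixed lists, the monoamine receptors fell in males. Of 21 measured genes in the list of serotonin, dopamine and adrenergic receptors, 3 fell, none rose and 18 did not pass, and 5 fell when adjusted over the list alone. The median log2 fold change was -0.48 (camera adjusted p = 1.93e-09, and adjusted p = 0.0338 with an estimated correlation). Htr1a headed it, followed by the adrenergic receptors Adra2c at -1.39 (adjusted p = 0.0184) and Adra2a at -1.13 (adjusted p = 0.0379). The list of anxiety and fear circuit genes, which shares Htr1a, also fell (1 of 31 members past the threshold, 6 adjusted over the list alone, median -0.21, adjusted p = 8.3e-05, and adjusted p = 0.0338 with an estimated correlation). Its neuropeptide Y receptors Npy1r and Npy2r had log2 fold changes of -1.23 and -1.10 (adjusted p = 0.16 and 0.119).

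Other male lists were called with the preset correlation alone. Clustered protocadherins, cell surface proteins that give neurons their identity, were the leading one: 48 of 53 members were lower, 1 fell past the threshold and 2 did when adjusted over the list alone (median -0.58, adjusted p = 4.19e-13, and adjusted p = 0.786 with an estimated correlation). Pcdha12 fell (log2 -2.12, SE 0.40, adjusted p = 0.0379). The values for Pcdhga12 and Pcdha10 were -1.14 and -1.59 (adjusted p = 0.13 and 0.174). Genes of the alpha and gamma clusters share their last exons, so their counts are uncertain. Axon guidance genes had 4 falls among 46 members, 6 adjusted over the list alone (adjusted p = 3.42e-07, and adjusted p = 0.296 with an estimated correlation), with Plxnd1, the ephrin Efna5 at -0.65 and Robo3 at -1.37. Immediate early genes had no member past the threshold, nor when adjusted over the list alone (median -0.54, adjusted p = 1.42e-06, and adjusted p = 0.735 with an estimated correlation). Their values included -1.11 for Npas4, -0.92 for Egr4 and -0.88 for Sik1. Interferon-stimulated genes were called higher with no member past the threshold, nor when adjusted over the list alone (median 0.40, adjusted p = 3.03e-07, and adjusted p = 0.624 with an estimated correlation), with values of 1.02 for Irf7 and 0.68 for Ifitm3.

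Lists of cell type and region markers were also called in males with the preset correlation. Excitatory neuron markers were lower (0 of 26 past the threshold, 2 adjusted over the list alone, median -0.28, adjusted p = 2.06e-05, and adjusted p = 0.165 with an estimated correlation), with Calb1 at -0.99, Lamp5 at -1.04 and Nnat at -0.76. Cortex markers were lower (0 of 20 past the threshold, 3 adjusted over the list alone, median -0.26, adjusted p = 6.63e-05, and adjusted p = 0.802 with an estimated correlation), with Ccn3 at -1.31 and Lmo4 at -0.82. Glutamate receptors were lower (0 of 24 past the threshold, 2 adjusted over the list alone, median -0.24, adjusted p = 6.18e-05, and adjusted p = 0.624 with an estimated correlation), with Gria2 at -0.32, Gria3 at -0.66 and Grm5 at -0.54. Nuclear oxidative phosphorylation genes were higher by a median of 0.13 (adjusted p = 8.3e-05, and adjusted p = 0.802 with an estimated correlation), with Cox5a at 0.30, Atp5b at 0.14 and Sdhd at 0.13. None of these genes passed the threshold in males. Astrocyte, leptomeningeal and microglia markers were called higher with medians of 0.14, 0.50 and 0.12 (adjusted p = 0.691, 0.802 and 0.735 with an estimated correlation). The leptomeningeal call was lost without cKO replicate 8 or 9 (adjusted p = 0.0897 and 0.294), the microglia call without WT replicate 1 (0.0541) and the oxidative phosphorylation call without cKO replicate 13 (0.0726). In all, 10 lists were called lower and 8 higher with the preset correlation, and 2 with the estimated one. The mean log2 CPM of oligodendrocyte markers ranged from 5.26 to 7.35 over male WT libraries and from 5.53 to 7.59 over male cKO libraries.

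The female comparison asked the same question in females. Ier5l fell 5.56-fold, from 31.6 ± 6.37 CPM in WT (SD, n = 5) to 5.68 ± 0.300 CPM in cKO (SD, n = 6), a log2 fold change of -2.47 (SE 0.13, adjusted p = 9.39e-07). Col6a2 fell 4.84-fold (log2 -2.27, SE 0.15, adjusted p = 9.96e-06), and Htr1a fell 4.35-fold (log2 -2.12, SE 0.32, adjusted p = 0.00267). Dkkl1 (log2 -2.08), Sstr1 (log2 -2.02), the collagen gene Col12a1 (log2 -2.01), Sstr2 (log2 -1.92) and Trabd2b (log2 -1.79) fell as well. Apart from Smc3, the largest rises among genes with a mean normalized count of at least 50 were those of the microRNA host gene Mir670hg at 1.27, the vesicular monoamine transporter Slc18a2 at 1.06, the centromeric histone variant Cenpa at 1.04, the perineuronal net link protein Hapln4 at 0.90, the Wnt agonist Rspo3 at 0.80, the glucocorticoid-activating enzyme Hsd11b1 at 0.80 and Pfkfb3 at 0.80. Of 16123 genes tested, 100 rose and 443 fell, 543 in all, and 2536 had an unadjusted p under 0.05. The authors' deposited table holds 858 genes under an adjusted p of 0.05 in females.

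**Figure D2:**
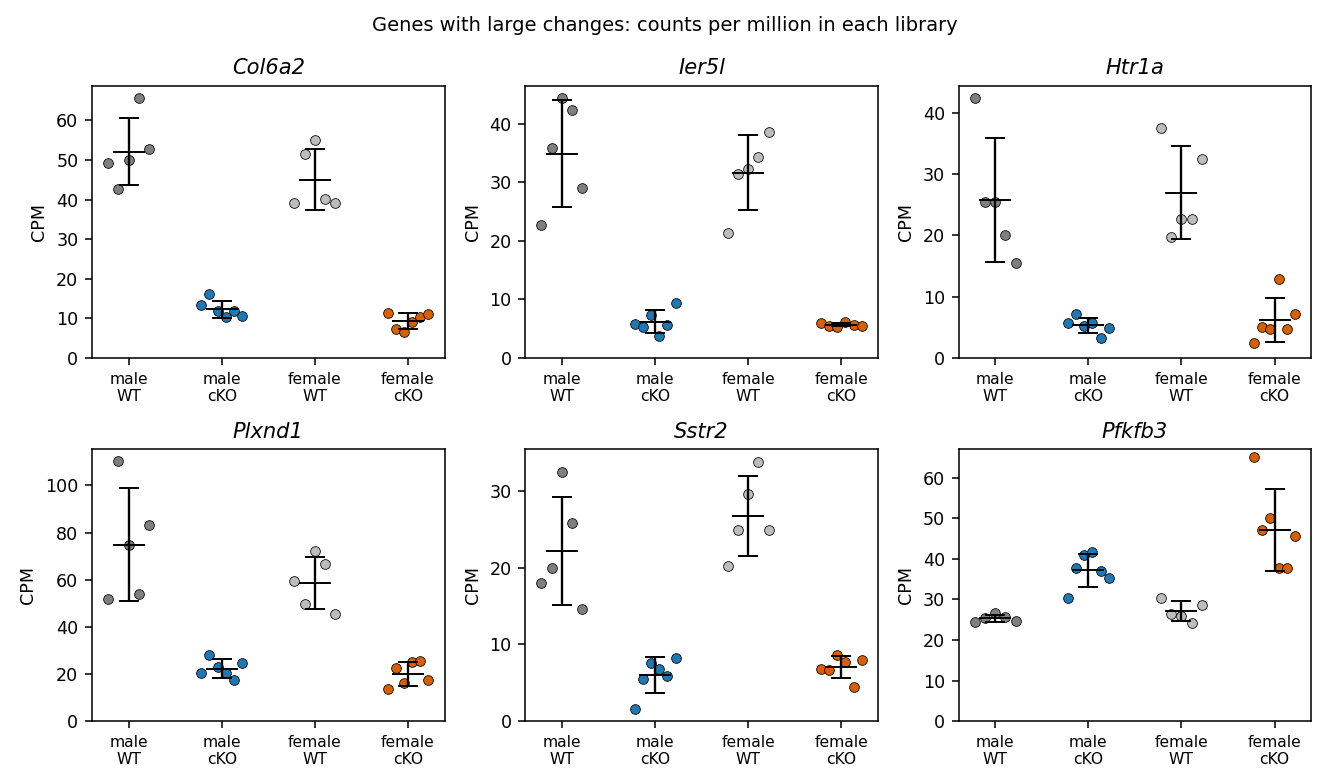
CPM (vertical axes, from 0) of 6 named genes in each library, by label. Points are libraries and bars are the mean and SD. The libraries labelled cKO and WT do not overlap in either sex for these genes, with mean Ier5l at 6.18 against 34.8 CPM in males and 5.68 against 31.6 CPM in females.

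The female count moved by over 1.5 times without cKO replicate 27, which left 360 calls, and without WT replicates 18 and 19, which left 341 and 324. DESeq2 called 894 genes, 254 rising and 640 falling, and one fit of all 4 groups called 294. Among 43 calls of named genes other than Smc3, 36 held with every library left out. Mir670hg, Slc18a2, Hapln4, Rspo3, Hsd11b1 and Sema3c were among those that did not. Cenpa, Crhr1, Crym, Hs3st4, Kcnt2 and Rasgrf2 held there and lost the call in one fit of all 4 groups.

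Lists of glutamate receptors, of monoamine receptors, of anxiety and fear circuit genes and of excitatory neuron markers were lower in females with both settings of the list test. The list of GABA receptors and synthesis was called lower with the preset correlation alone (adjusted p = 0.00264, and adjusted p = 0.347 with an estimated correlation). Of 24 glutamate receptor genes, 8 fell, none rose and 16 did not pass, with 10 falling when adjusted over the list alone (median -0.30, adjusted p = 5.34e-11, and adjusted p = 0.00457 with an estimated correlation). The AMPA receptor subunits Gria2 and Gria3 fell (log2 -0.35, SE 0.06, adjusted p = 0.00528, and log2 -0.73, SE 0.10, adjusted p = 0.00152), as did the kainate receptor subunit Grik4 (log2 -0.77, SE 0.09, adjusted p = 0.000307). In the serotonin, dopamine and adrenergic receptor list 5 of 21 fell, 7 adjusted over the list alone (median -0.28, adjusted p = 1.08e-05, and adjusted p = 0.0144 with an estimated correlation), with Htr2a at -1.63 (adjusted p = 0.00428) and the dopamine receptor Drd5 at -1.15 (adjusted p = 0.00532). Of 32 anxiety and fear circuit genes, 9 fell and none rose, 10 adjusted over the list alone (median -0.13, adjusted p = 5.13e-08, and adjusted p = 0.00457 with an estimated correlation). They included the corticotropin-releasing hormone receptor Crhr1 at -1.57 (SE 0.17, adjusted p = 0.000253), along with Htr1a and Htr2a. Excitatory neuron markers fell as a list (7 of 26 fell, 12 adjusted over the list alone, median -0.33, adjusted p = 1.72e-09, and adjusted p = 0.0281 with an estimated correlation), with Hs3st4 at -0.52, Calb1 at -1.01 and Crym at -0.66. One of them rose when adjusted over the list alone.

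The clustered protocadherins were the leading list in females too. Of 53 members 49 were lower, 16 fell past the threshold and 34 did when adjusted over the list alone (median -0.61, adjusted p = 9.1e-23, and adjusted p = 0.159 with an estimated correlation). By cluster, 2 of 11 alpha, 8 of 21 beta and 6 of 21 gamma genes fell, with medians of -0.876, -0.515 and -0.658. Falls were seen for Pcdha12 (log2 -2.17, SE 0.27, adjusted p = 0.00068), Pcdhb20 (log2 -0.90, SE 0.12, adjusted p = 0.00136) and Pcdhb22 (log2 -0.99, SE 0.15, adjusted p = 0.00255). The difference between sexes for this list had an adjusted p of 0.902. Potassium channels had 6 falls among 41 members, with 16 falls and 1 rise adjusted over the list alone (adjusted p = 4.98e-06, and adjusted p = 0.724 with an estimated correlation), with Kcng1 at -0.92, Kcnh1 at -0.89 and Kcnt2 at -0.53. Axon guidance genes had 4 falls and 1 rise among 46, and 12 falls and 1 rise adjusted over the list alone (adjusted p = 1.67e-05, and adjusted p = 0.241 with an estimated correlation). Plxnd1 (log2 -1.55), Plxna1 (log2 -0.50) and Sema3c (log2 -0.57) fell. Postsynaptic scaffold genes were called lower (1 of 29 fell, 7 adjusted over the list alone, adjusted p = 0.000208, and adjusted p = 0.761 with an estimated correlation). Lrrtm4, a postsynaptic adhesion protein, fell by 0.77, and Homer2 and Nlgn3 had values of -0.38 and -0.28 (adjusted p = 0.0676 and 0.0789). Cortex markers were called lower (5 of 20 fell, 9 adjusted over the list alone, adjusted p = 1.35e-08, and adjusted p = 0.613 with an estimated correlation), with Ccn3 at -1.29 and Rasgrf2 at -0.58.

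Some lists were called higher in females, none with an estimated correlation. Cholesterol synthesis genes had a median of 0.24 (0 of 20 rose, 4 adjusted over the list alone, adjusted p = 0.000302, and adjusted p = 0.819 with an estimated correlation). Its members Dhcr7 and Msmo1 had values of 0.27 and 0.31 (adjusted p = 0.0644 and 0.124). Oligodendrocyte markers were higher by a median of 0.41 (0 of 22 past the threshold, adjusted p = 0.000302, and adjusted p = 0.819 with an estimated correlation), and astrocyte markers by 0.09 (adjusted p = 0.0285, and adjusted p = 0.819 with an estimated correlation). Choroid plexus and ependymal markers had a median of 0.54 (adjusted p = 0.0132, and adjusted p = 0.819 with an estimated correlation). That call was lost without cKO replicate 21 (adjusted p = 0.217), in which the choroid plexus gene Ttr, chosen after its values were seen, stood at 528 CPM, and without WT replicate 25 (0.24). Without WT replicate 25 the oligodendrocyte and astrocyte calls were lost too (0.0528 and 0.24), and the astrocyte call also without cKO replicate 20 or 23 (0.0582 and 0.0931). In all, 13 lists were called lower and 7 higher with the preset correlation, and 4 with the estimated one. The list of cohesin partners and regulators, without Smc3, was not called in either sex (adjusted p = 0.369 in males and 0.131 in females). In females Pds5b fell by 0.46 while Stag1 rose by 0.31 and Hdac8 rose by 0.42, 3 genes chosen after their values were seen.

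**Figure D3:**
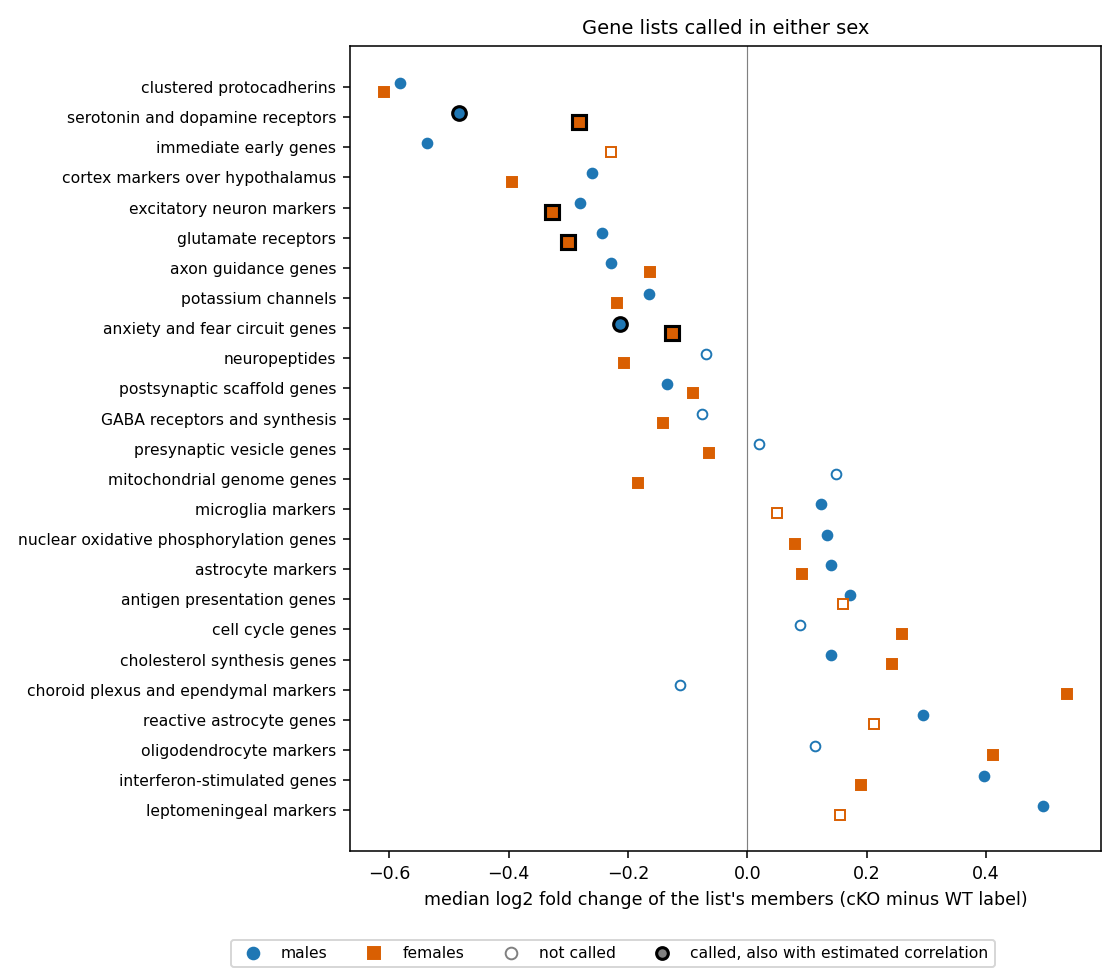
Median log2 fold change (horizontal axis, cKO minus WT label) of the members of the 25 lists called in either sex, with circles for males and squares for females. Filled symbols are calls with the preset correlation, and a black edge marks those that also held with an estimated correlation, which are 2 lists in males and 4 in females.

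The third comparison asked whether the cKO effect differs between males and females. No gene passed. Of 16855 genes, edgeR called 0 for the genotype by sex term, with 176 under an unadjusted p of 0.05 and a smallest adjusted p of 1, and DESeq2 called 0 with 245 under an unadjusted p of 0.05. The 10 genes with the smallest p were Axin2, Platr25, Tmem204, Prcp, Map3k14, Dmrta2, Tmem138, Pyurf, Itpkc and Eps8l1. Axin2, a target of Wnt signalling, had the smallest p (adjusted p = 1), with a log2 fold change of -0.15 in males and 0.13 in females. The largest difference among the 10 was 0.86 for Eps8l1 (female minus male, SE 0.33, adjusted p = 1). The 176 genes are 1.04% of those tested, below the share of 0.05 that chance alone would give. Genes vary together, so this share does not show by itself how strict the test was. Among other groupings of the libraries the highest count for this test was 2064. The lack of calls does not show that the sexes respond alike. The test recovered 23.1% of simulated 1.5-fold differences and 56.9% of 2-fold ones. Each gene was simulated on its own, so these shares may overstate the recovery in the real libraries.

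Most genes called in 1 sex had the same direction in the other. Among 15787 genes tested in both sexes, 57 fell in both, where independent lists would share 2.24 (Fisher's exact test, 2-sided p = 3.47e-71), and 9 rose in both, where they would share 0.0807 (p = 6.58e-18). The test takes genes as independent, which they are not, so these p-values do not measure the spread between animals. Without male cKO replicate 8 the shared falls and rises were 106 and 19. Without male cKO replicates 9, 10, 12 and 14 the falls were 18, 19, 15 and 20 and the rises 3, 4, 3 and 5, and without male WT replicates 3, 4, 5 and 6 the falls were 15, 15, 28 and 21 and the rises 3, 3, 4 and 4. No gene was called in both sexes with opposite signs. The 10 shared genes with the strongest evidence in both sexes were Col6a2, Ier5l, Plxnd1, Htr1a, Smc3, Wnt7b, Dpy19l1, Clcn2, St3gal1 and Ptpru. The Wnt ligand Wnt7b fell in males (log2 -1.29, SE 0.14, adjusted p = 0.00287) and in females (log2 -1.59, SE 0.17, adjusted p = 0.000236). The chloride channel Clcn2 had log2 values of -0.71 in males and -0.62 in females, and the sialyltransferase St3gal1 -1.23 and -1.25. The receptor phosphatase Ptpru fell 2.06-fold in males, and Dpy19l1 fell 1.99-fold in males and 1.80-fold in females. A further 475 genes passed in the female fit alone and 27 in the male fit alone. Of the 541 genes called in females and tested in males, 536 had the same sign in males, and all 93 genes called in males and tested in females had the same sign there. Over the 541 genes, which were chosen by their female p and so favour the female size, the median size of the log2 fold change was 0.64 in females and 0.52 in males, with median standard errors of 0.12 and 0.19, and the slope of male on female values was 0.804. Over the 93 genes chosen by their male p the slope of female on male values was 0.966.

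Across 15670 genes the log2 fold changes of the sexes correlated with a Pearson r of 0.657 and a Spearman rho of 0.556. This r is across genes, which are not independent replicates. Its jackknife standard error over the libraries was 0.215. With the preset correlation, 11 lists differed between the sexes, led by the genes of the mitochondrial genome (median -0.32, female minus male, adjusted p = 1.6e-08) and striatum markers (median 0.31, adjusted p = 0.000114). With an estimated correlation no list differed (adjusted p = 0.968 for both), and the striatum call was lost without male cKO replicate 8 (adjusted p = 0.0813).

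**Figure D4:**
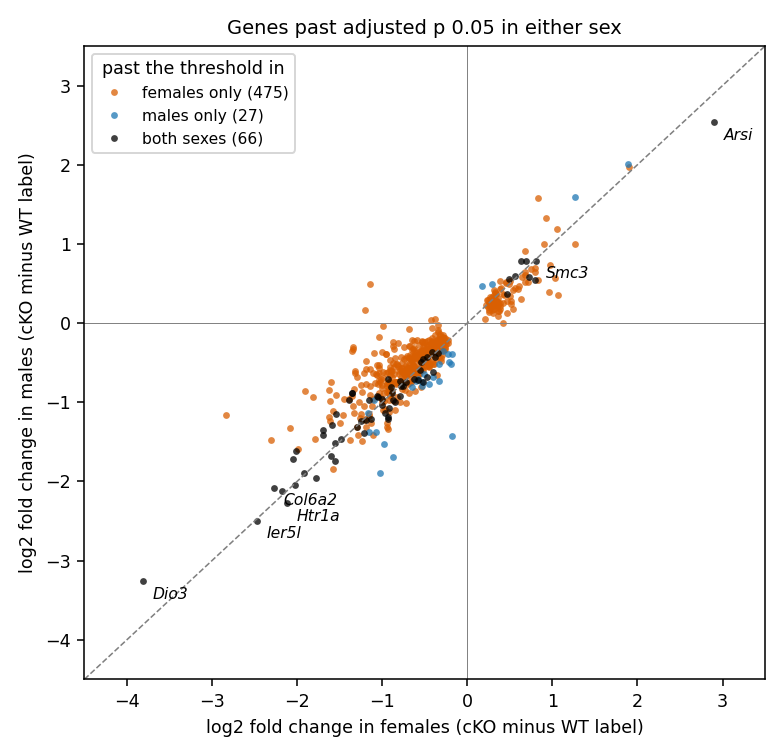
Log2 fold change (cKO minus WT label) in females on the horizontal axis and in males on the vertical axis for the 568 genes past an adjusted p of 0.05 in either sex, coloured by the sex in which they passed. The dashed line marks equal values, and 536 of the 541 genes called in females lie on the same side of 0 in males.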

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

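The test based on Arsi, that of Smc3 under other scalings and the use of the planned single fit of both sexes to compare their counts were chosen after the result was seen, and the other tests below before.

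Smc3 rose in the libraries labelled cKO of both sexes, where a deletion that lowers the gene's total would give a fall. Whether the deletion lowers that total is not known here. A scaling difference between libraries is argued against, since Smc3 was higher by at least 0.786 in counts without any scaling and under library totals, upper-quartile and RLE factors, while the median of well-measured genes in unscaled counts moved by 0.0797 in males and 0.0369 in females. Labels exchanged between the groups remain open, and an exchange would turn every direction in the report. Arsi, the gene next to Camk2a, was at least 2.54 higher on the log2 scale in the libraries labelled cKO and ranked 1 of 16098 genes by rise in males and 2 of 16123 in females, as it could if it came along with a Camk2a transgene. Around it the values were mixed, with Slc6a7 on the other side of Camk2a at 0.37 in males (adjusted p = 0.483) and 0.17 in females (0.589), Cd74 on the side of Arsi at 0.91 (0.394) and 0.68 (0.0253), Tcof1 between them at 0.07 (0.946) and 0.08 (0.656), and Camk2a itself at -0.14 (0.932) and -0.23 (0.391), and what the transgene carries is not known here, so the question cannot be told apart from these tables, and a counted transcript without the floxed part was not tested.

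Most called genes were lower in the libraries labelled cKO, 86.2% of the calls in males and 81.6% in females. Scaling is argued against, with at least 78.1% falling under no scaling, upper-quartile and RLE factors. A GC or length trend is argued against as the whole cause, with at least 75.2% falling after it was taken out of each library. A general loss of excitatory neurons was predicted to give a value near 0 for falling genes relative to excitatory markers. Genes called lower in 1 sex, measured in the other, lay below the excitatory markers by -0.328 in males (SE 0.0864, exact permutation p = 0.0108). In females they lay below by -0.64 (SE 0.0462, exact permutation p = 0.00216). These genes were chosen for their falls and the markers were not, so such a loss could also give a value below 0. The test therefore cannot decide the question. A general loss, a loss or a change within some excitatory neurons, and a biological effect of the genotype remain possible.

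Females gave 543 calls and males 94. Depth is argued against, since female libraries thinned to the mean male total still gave 529 calls. A larger spread between male libraries is consistent with the tables: the common dispersion was 2.34 times that of females, and in one fit with a shared spread the female to male ratio of calls was 1.07 where separate fits gave 5.78. A larger effect in females remains open. Over 1201 genes called for the average effect, the ratio of male to female effect was 1.001 with a jackknife standard error of 0.116. That does not exclude a modest difference. The genes were chosen by that average in the same libraries, where males spread more, so the ratio may favour the male size. The jackknife does not measure such a shift. No gene passed the test of the difference itself.

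Other groupings of the same libraries bear on each count. Each set of 100 splits below holds the real grouping and 99 others. In males 4 of 100 splits, the real one among them, gave at least the real 94 calls. In females 2 of 100, again with the real one, gave at least the real 543. Both shares lie under the 5% level, so chance is argued against. In males this is weak, since the share lies close to that level and comes from 100 of 462 possible splits. The highest other splits gave 1721 and 711 calls, several times the real count in males, which points to a structure of the samples. In males the 2 splits that parted the oligodendrocyte marker score most, by -1.35 and 1.26 (real split 0.176), gave 897 and 1721 calls, so the structure may follow the share of oligodendrocyte RNA. Male splits that parted it by 1.1 and -1.06 gave 0 calls and one at -0.495 gave 111, and the highest female split stood at -0.482 (real split 0.417). Among other splits with at least 20 calls, at most 63.4% fell in males and 46% in females. Calls could also lean to the rising side: the male split with 111 calls had 74 rises, and a female split with 42 calls had 38. In both of these all 5 WT libraries had changed sides, which nearly reverses the real grouping. For the difference between sexes the splits decide nothing, since any split gives at least the real 0 (100 of 100, highest other 2064). Chance is not excluded for the number of called lists: with the preset correlation 47 of 100 male splits gave at least 18 (highest other 26), 49 of 100 female splits at least 20 (highest other 30) and 87 of 100 at least 11 for the difference (highest other 27). With an estimated correlation 2 of 100 male splits, the real one among them, gave at least 2 lists (highest other 2). In females the real split alone gave at least 4 (1 of 100, highest other 1). Both shares lie under the 5% level, so there chance is argued against.

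With the preset correlation 11 lists differed between the sexes by a test of the difference, and with an estimated correlation each had an adjusted p of 0.968. Higher in the female effect were striatum markers (adjusted p = 0.000114), choroid plexus and ependymal markers (0.00231), oligodendrocyte markers (0.0159), imprinted genes (0.0204), immediate early genes (0.0213) and hypothalamus markers (0.024). Immediate early genes turned direction without female cKO replicate 24 (adjusted p = 0.717, with 4.18e-06 to 0.741 over the libraries left out), and the choroid plexus call was lost without female cKO replicate 21 (0.134), among others. Lower were mitochondrial genome genes (1.6e-08), leptomeningeal markers (0.0116), endothelial and mural markers (0.0159), microglia markers (0.0212) and interferon-stimulated genes (0.0213). Of the 11, mitochondrial genome genes alone passed with each library left out.

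Single libraries stood apart from the rest of their group in 20 of 230 combinations of a named gene and a group, 8.7%, where chance gives about 1 in 20. In CPM, with the nearest library of the group second, cKO replicate 8 in males was highest for Smc3 (172 and 146) and Efna5 (15.4 and 11.9) and lowest for Wnt7b (11.7 and 16.9) and Ptpru (20.5 and 26.3). Male WT replicate 1 was highest for Adra2a (59.8 and 30.7), and the male WT replicate 6 value for Tmem204 was highest at 7.09 with 5.52 next. In females cKO replicate 24 was highest for Calb1 (107 and 73.3), Gria3 (198 and 165) and Kcnh1 (40.9 and 32.3) and lowest for Grik4 (17.7 and 22). Female cKO replicate 27 was highest for Smc3 (149 and 129), cKO replicate 20 for Mir670hg (26.4 and 13.8), and cKO replicate 21 was lowest for Sema3c (13 and 19.5). Female WT replicate 26 was highest for Hsd11b1 (16.6 and 10.5), Lrrtm4 (30.4 and 23.5) and Nlgn3 (78.6 and 68.3). Female WT replicate 25 was highest for Hapln4 (75.1 and 62.0) and lowest for Axin2 (25.4 and 29.5) and Dmrta2 (2.91 and 3.66), and WT replicate 16 was lowest for Hs3st4 (82.0 and 101).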

How the results depend on the processing

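The oligodendrocyte marker covariate, DESeq2 and RLE for the difference between sexes, one fit of all groups for the overlap, the alternatives for Smc3 other than centring and leaving out libraries, and leaving out libraries for lists, overlap, correlation and the difference were added after seeing the data, and the rest was planned. Smc3 stayed higher under the alternatives run and passed the threshold in each of them except Bonferroni in males, from 0.72 to 0.85 in males and 0.75 to 0.85 in females with a library left out. No alternative run gave a gene that differed between the sexes.

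The male count of 94 was 170 at an adjusted p under 0.1, 15 under 0.01, 10 with Bonferroni, 327 with DESeq2, 276 in one fit of all groups and 273 with the covariate, and 18 to 201 with a library left out. The female count of 543 was 880, 188, 44, 894 and 294 under the same first 5 settings, 359 with a log2 fold change of at least 0.5, and 324 to 681 with a library left out. With DESeq2 the split was 96 rising and 231 falling in males and 254 and 640 in females, against 13 and 81 and 100 and 443. Stricter thresholds call fewer genes by construction. The cause of the other shifts was not tested.

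The shared rising and falling genes, 9 and 57, were 19 and 108 at an adjusted p under 0.1, 70 and 270 at an unadjusted p under 0.01, 29 and 193 among the genes with the smallest p of each sex, 17 and 150 in one fit, 19 and 146 with the covariate, and 3 to 19 and 15 to 106 with a library left out. The correlation of 0.657 ranged from 0.556 to 0.778 over the planned settings and from 0.558 to 0.739 with a library left out. Its jackknife standard error over the libraries, 0.215, is wider than these ranges may convey.

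Lists called with a preset correlation of 0.05 were 13 in males, 13 in females and 3 for the difference. With an estimated correlation they were 2, 4 and 0. With a library left out they were 13 to 22, 15 to 24 and 5 to 15. The difference for immediate early genes turned direction without female cKO replicate 24 (adjusted p = 0.717, with a range of 4.18e-06 to 0.741 over the libraries left out), the cause of which was not tested. Of the named genes called, 11 of 26 in males and 30 of 43 in females held with each library left out and, where tested, under no filter, a higher minimum count, RLE, the covariate, DESeq2 and one fit of all groups, without a change of sign. Stricter thresholds are not part of that count. The alternative meant for tables of statistics alone was not run, since counts were at hand. No paired analysis was possible because no number is shared between groups.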

Other observations

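The tests of neighbouring genes and of gene length were set out before their results were seen. The effect averaged over both sexes, and the genes named here, were chosen after the values were seen.

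Averaging the effect over both sexes in the fit of all 22 libraries called 1201 genes, 414 higher and 787 lower in the libraries labelled cKO, and 701 of them were called in neither sex alone. Other groupings, other methods and leaving out a library were not run for this count. The fit shares a spread between the sexes, although the common dispersion in males was 2.34 times that of females. Dio3, the imprinted gene of the enzyme that inactivates thyroid hormone, fell by 3.54 (SE 0.25, adjusted p = 9.99e-09), below the abundance needed for the named genes of either sex. Of the clock gene list 5 rose and 4 fell, and the list was not called (adjusted p = 0.741): Npas2 (-0.73) and Nr1d1 (-0.40) fell, while Cry1 rose by 0.29 and Nfil3 by 0.53. The opioid receptor gene Oprk1 (-1.22) and the oxytocin receptor gene Oxtr (-0.93) fell. The activity-regulated gene Arc fell by 1.12. Gfap, the intermediate filament of astrocytes, rose by 0.88 (adjusted p = 0.000941).

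Of the lists, 3 were called for the average effect with an estimated correlation. These were anxiety and fear circuit genes (10 of 32 fell, adjusted p = 0.00197), serotonin, dopamine and adrenergic receptors (6 of 22 fell, adjusted p = 0.00295) and excitatory neuron markers (6 of 26 fell, adjusted p = 0.0253).

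A hypothesis for a cohesin gene is that neighbouring genes fall together. With clustered protocadherins left out, 19 pairs of neighbouring protein-coding genes both fell in females, where 10000 random draws gave a mean of 11.4 and as many in 2.16% of draws, and 1 pair fell in males, where draws gave as many in 30.4%. The pairs included Col6a2 with Col6a1, Neto1 with Cbln2 and Lypd6b with Lypd6. The female count alone is in line with the hypothesis, and with 71 falling genes in males the test there has little reach, so it remains open.

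A second hypothesis is that longer genes fall more often. Genes that fell in females had a median genomic length of 54.7 kb, above the range of 21.5 to 28.8 kb of sets matched on expression (median 25 kb). In males the median was 22 kb, within the range of 16.2 to 33 kb. The difference between the sexes in this measure was not tested, and the hypothesis remains open.

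Ttr, the main transcript of the choroid plexus, was at 528 CPM in female cKO replicate 21, where the other 5 female cKO libraries stood at 1.75 to 6.43 CPM, no female WT library exceeded 5.99 CPM and no male library exceeded 2.19 CPM.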
